A study of Homo sapiens and Homo sapiens
Mus musculus with 19 samples.

How the data were processed

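The series holds 19 samples of established breast cancer lines, 10 with RNA tables and 9 with tables of antibody tags. Cells were grown in DMEM with 10% fetal bovine serum, and drug-treated SK-BR-3 cells received trastuzumab for 72 h, per the labels, which give no dose. Groups and replicate numbers were taken from the labels. There were 4 groups of 2 libraries (MCF7, SK-BR-3, MDA-MB-231 and treated SK-BR-3), each RNA library with its own antibody table, and a mixture of human MCF7 and mouse 4T1 cells in 1 multi-omics and 1 single-omics library.

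The deposited tables hold whole-number counts per gene and barcode, or per antibody tag and barcode, with no normalization by the authors visible in the values. The antibody tables also hold a tag named for mouse IgG1, which is called the IgG control here although the labels do not state its role. The submitters' processing notes name STAR and the builds hg19 (GRCh37) and mm10 (GRCm38). The STAR version, the annotation, the counting tool, the rule that chose barcodes, and whether reads were collapsed by molecular identifier are not given in the sources used here. Nor is the way antibody tags were counted. Without knowing that reads were collapsed, counts may not be independent molecules, so all counting intervals and floors cover counting error only. Whether counting used strand is not given either, so overlapping genes and their antisense partners cannot be told apart. Genes were used by the symbols in the tables, and no genome was used.

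Barcodes with at least 500 detected genes were kept. No doublet caller was run, because the single-line libraries hold 1 line each, and the share of barcodes with RNA of both species in the mixture is reported in its place. In the mixture a barcode was called human or mouse when at least 90% of its counts came from that species. Counts were summed per library, since barcodes are not replicates. Kept barcodes held 1399259 to 8020833 counts per library. The sums were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood, robust, TMM scaling, low-count filter by group) in 1 fit over the 8 libraries with 4 residual degrees of freedom, at a Benjamini-Hochberg adjusted p of 0.05. With 2 libraries per group the estimate of spread is shared by the 4 groups. Standard errors are those of log2 fold changes, and CPM are TMM-scaled. A gene with no count in a group was set against a floor of 3 counts over the group, and a gene with 1 to 3 counts is given as a ratio with an exact 95% counting interval.

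Before the data were examined, gene lists, the tests, the main alternatives and the rule for named genes were fixed. Of 30 lists, the 28 with at least 5 tested members entered camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over these lists within each comparison, with camera at an estimated correlation and fry beside it. Fry tests whether the genes of a list move on balance in a common direction and does not compare them with other genes. The rule named up to 8 genes each way with the highest and lowest log2 fold change among those called, with a mean of at least 50 CPM in the higher group and libraries that did not overlap. It added the genes of the 3 antibody targets and up to 4 called members of each list described, those with the largest absolute change. The rule did not fix which lists were described, and some that passed camera are counted but not described. In the mixture it took EPCAM, Epcam and the 5 genes with the largest ratio each way per species among those with at least 50 counts in the higher library. XIST met the rule and was left unnamed.

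Antibody tags were averaged per barcode and library, and log2 means were compared across the 4 groups with an exact permutation F test over all partitions, whose smallest p is 0.00952. Two-sided exact tests of 2 libraries against 2 cannot go below p = 0.333, so pairs of groups were not tested. Within each library the Spearman correlation of EPCAM, ERBB2 and EGFR RNA (scaled to 10000 counts, log2 with a pseudocount of 1) with log2 tags was compared with the 6 mismatched pairs, using a two-sided exact sign-flip test over the 8 libraries (256 patterns, smallest p 0.0078). Shares have exact (Clopper-Pearson) 95% intervals, and medians have order-statistic intervals. Depth was equalised where stated by drawing 1000 counts from each barcode. The mixture has 1 library of each kind, so no p was computed between them. The Pearson correlations across genes used log2(CPM + 1). Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

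The fit was tested on simulated counts with 200 genes changed, in a single run per comparison. Shares recovered are of the changed genes that passed the low-count filter, 36 to 49 per fold and comparison. For treated against untreated SK-BR-3 (10546 simulated genes) it recovered 6.52% of genes changed by 1.5-fold, 46.2% by 2-fold, 88.9% by 4-fold and 97.8% by 8-fold, and 10.1% of its calls were false. For SK-BR-3 against MCF7 (10656 genes) the shares were 11.1%, 42.2%, 86.0% and 97.9% with 10% false calls. For MDA-MB-231 against MCF7 (10858 genes) they were 13.0%, 61.4%, 90.9% and 95.3% with 8.8% false, and for MDA-MB-231 against SK-BR-3 (11190 genes) 14.6%, 44.9%, 97.9% and 100% with 8.89% false. False calls were thus above the nominal 5% in each simulation, but each share rests on only 11 or 12 false calls. Far fewer genes were changed than edgeR called in the real comparisons, so these shares may not carry over to them. With no effect the exact F and sign-flip tests passed in 3.25% and 3.5% of 400 simulations.

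Alternatives were DESeq2 1.42.0, median-of-ratios scaling, no low-count filter, all barcodes or those with at least 1000 genes, libraries thinned to the smallest, only the groups compared, the replicate number as a block, each library left out in turn, other tag and correlation scales, and other species thresholds. Chosen after the data were seen were the ratio to the IgG tag and the removal of barcodes that hold an undetermined base or occur in several libraries. Where a library is left out, the lone library of its group is assumed to vary like the other groups.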

Results

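Messenger RNA and antibody-bound surface protein were counted in single cells of breast cancer lines. MCF7 is an oestrogen receptor-positive line, SK-BR-3 carries an amplified ERBB2 gene, which encodes the receptor HER2, and MDA-MB-231 is a line with mesenchymal features. Each of these lines gave 2 multi-omics samples, and SK-BR-3 cells exposed to trastuzumab, a therapeutic antibody against HER2, for 72 h gave another 2. Counts here are those of the tables, and whether reads were collapsed by molecular identifier is not given in the sources used here. Every multi-omics sample has an RNA table and a table of DNA-barcoded antibodies against EpCAM, HER2 and EGFR plus an IgG control. A mixture of MCF7 with the mouse mammary line 4T1 was run once with protein capture (multi-omics) and once for RNA alone (single-omics).

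Depth differed between libraries. Among barcodes with at least 500 detected genes, the RNA libraries held 739 and 990 barcodes for MCF7, 976 and 869 for SK-BR-3, 562 and 980 for MDA-MB-231, and 276 and 732 for treated SK-BR-3. Their total counts ran from 1399259 in treated SK-BR-3 replicate 1 to 8020833 in MDA-MB-231 replicate 2. Median counts per barcode were 2221 and 2573.5 in MCF7, 2500.5 and 2340 in SK-BR-3, 6836 and 6540.5 in MDA-MB-231, and 2535.5 and 3018.5 in treated SK-BR-3. Mitochondrially encoded genes took 1.86% and 2.39% of the counts in MCF7, 2.11% and 5.07% in SK-BR-3, 4.08% and 4.15% in MDA-MB-231, and 6.97% and 7.49% in treated SK-BR-3. Replicates of every group differed by more than sampling noise, with a chi-square per degree of freedom between 4.69 and 13.1. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

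How often a barcode carried RNA of both species was read from the cell mixture. In the multi-omics library 832 of 1179 barcodes were human and 334 were mouse, and 13 (1.10%, exact 95% binomial interval 0.588 to 1.88%) held under 90% of either species. In the single-omics library 862 of 1537 barcodes were human and 674 were mouse, and 1 (0.0651%, interval 0.00165 to 0.362%) was mixed. The mixed share of the multi-omics library was 3.22% at a species threshold of 95% and 1.94% among barcodes with at least 1000 genes. Counts of the other species made up a median of 0.0969% and 0.473% in human and 2.24% and 1.87% in mouse barcodes of the multi-omics and single-omics libraries. With 1 library of each kind, no test between them was made.

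The median human barcode held 1873 counts in the multi-omics library and 3498.5 in the single-omics library, a ratio of 0.535, and 1079.5 against 1557.5 detected genes. Bounds of 0.473 and 0.628, set by the 95% order-statistic intervals of the medians, cover the spread between barcodes within 1 library each. Among human barcodes with at least 1000 genes the ratio of median counts was 0.845. Mouse barcodes held 1898 and 1634 counts, a ratio of 1.16 whose bounds of the same kind, 0.960 and 1.35, include no difference. Thinned to 1000 counts per barcode, which left out 131 and 45 human barcodes, the multi-omics and single-omics libraries gave 673 and 648 genes per human barcode. The same thinning left out 58 and 135 mouse barcodes and gave 717 and 741 genes.

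Summed expression profiles of the mixture libraries had a Pearson correlation of 0.957 across 22141 human genes and 0.908 across 15617 mouse genes, on log2 values, where genes are not independent replicates. Among genes with at least 50 counts in the higher library, 1306 of 6999 human and 1799 of 5045 mouse genes differed by over 2-fold. EPCAM, the gene of the captured antigen, was 1.34 times as high in the multi-omics library (counting interval 1.25 to 1.45), and mouse Epcam was 1.44 times as high (1.2 to 1.73). The rule named 5 human genes that were lower with protein capture. The brain cytoplasmic RNA BCYRN1, which has many near-identical copies in the genome, had 19 counts against 1363 (0.0210 times as high, 0.0126 to 0.0329). The mitochondrial transfer RNA genes MT-TP and MT-TF had 15 against 971 and 8 against 376. MT-TS2 had 1 count against 141 (0.0107 times, 0.000269 to 0.0605). The pseudogene HMGB1P8 had 1 against 145 (0.0104 times, 0.000261 to 0.0588). Reads of copies and pseudogenes can be shared with their parent genes, so these counts are uncertain. The linker histone genes HIST1H1B and HIST1H1D, members of a family with similar copies, were 7.41 (3.94 to 15.1) and 5.21 (3.86 to 7.12) times as high with protein capture. TMED7, FAM208A and LNPEP were 5.36, 5.02 and 4.60 times as high. Among mouse genes Fam193b had 2 counts against 236 (0.0114 times, 0.00138 to 0.0418), Mir5136 had 3 against 215 (0.0188 times, 0.00386 to 0.0558). Suv420h2 had 2 against 130 (0.0208 times, 0.00249 to 0.0766) and Trpv4 had 5 against 226. Snhg9 was at 0 against 144, at least 35.5-fold lower against a floor of 3 counts in the library. Mir5136 and Snhg9 lie within or beside other genes, so reads could be shared. Prl2c3, one of several similar genes (55 counts against 2, 37.1 times, 9.81 to 314), Id2 (15.6 times, 7.25 to 40.1), Serpine1 (8.73 times), Polr2d (8.61 times) and Ppp4c (8.44 times) were higher with protein capture. These ratios compare a single pair of libraries and their intervals cover counting error only.

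The antibodies against human and mouse EpCAM, an epithelial adhesion molecule, gave different contrasts between the species in raw tags. Human barcodes carried a mean of 9.81 human and 6.48 mouse EpCAM tags, and mouse barcodes 6.35 human and 40.4 mouse tags. The tag of the own species was the larger in 70.1% of the 832 human barcodes (exact 95% binomial interval 66.8 to 73.2%, 61 ties) and in 100% of the 334 mouse barcodes (98.9 to 100%). In raw means, the human tag was 1.54 times and the mouse tag 6.24 times as abundant on the own species as on the other. The IgG control averaged 0.475 tags on human and 1.56 on mouse barcodes. Scaling to IgG would therefore raise the contrast of the human tag and lower that of the mouse tag. Which antibody is the more specific stays open.

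SK-BR-3 and MCF7 differed in genes of the HER2 amplicon, oestrogen receptor targets and apocrine genes. All 16 measured genes of the amplified segment around ERBB2 were higher in SK-BR-3, with a median log2 fold change of 4.31. ERBB2 itself stood at 453 ± 92.4 CPM (TMM-scaled counts per 1e6; SD, n = 2) against 6.33 ± 0.674, a log2 fold change of 6.14 ± 0.26 (SE). Its neighbour GSDMB had 2349 counts in SK-BR-3 against 3 in MCF7, a ratio of 785 (counting interval 268 to 3811). Oestrogen receptor targets were lower: TFF1, which encodes a secreted trefoil peptide, by −8.56 ± 0.36 on the log2 scale and TFF3 by −6.13 ± 0.34. The secretory genes SCGB2A2, which encodes mammaglobin, and PIP were undetected in MCF7 and at least 111-fold and 14.7-fold higher in SK-BR-3, against a floor of 3 counts over the group.

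By list, with p-values adjusted over the 28 lists tested in each comparison, the HER2 amplicon had an adjusted p of 3.5e-12 (camera with a preset correlation), and adjusted p = 0.056 with an estimated correlation. Of 21 oestrogen receptor and luminal genes 13 fell and 4 rose (adjusted p = 8.3e-04, and adjusted p = 0.11 with an estimated correlation). IGFBP4 was at least 60.2-fold lower and CXCL12 was lower by a ratio of 66.8 (22.5 to 327). Of 13 apocrine and androgen receptor genes 9 rose and 2 fell (adjusted p = 0.0012, and adjusted p = 0.13 with an estimated correlation). DHRS2, which encodes a dehydrogenase, was at 7.33 ± 0.29 and APOD at 6.65 ± 0.32. Of 53 genes of the G2 and M phases 34 were lower and 4 higher in SK-BR-3 (adjusted p = 1.5e-05, and adjusted p = 0.11 with an estimated correlation). Among them were NDC80 at −2.93 ± 0.22, ANP32E at −2.76 ± 0.21, AURKB, which encodes a mitotic kinase, at −2.56 ± 0.19 and DLGAP5 at −1.86 ± 0.21. Adjusted over the list alone, the counts were 16 higher, 13 lower, 9 higher and 35 lower for these lists in turn. Beyond the lists, LDHB, CTSZ, LCN2, FBLN1, ALDH2 and CPVL had no count in MCF7 and were at least 2404-, 840-, 704-, 470-, 365- and 278-fold higher in SK-BR-3. MAGEA3, a gene with near-identical copies whose count is therefore uncertain, was at least 233-fold higher. AC099850.1, which is uncertain because its reads may belong to an overlapping gene, PYCARD, KCNK15, OLFM1 and DKK1 had no count in SK-BR-3 and were at least 302-, 265-, 202-, 164- and 120-fold lower. AKAP12 and SUSD3 were lower by ratios of 2146 (594 to 17726) and 779 (139 to 30794). EGFR was higher in SK-BR-3 by 4.51 ± 0.48, and EPCAM did not pass the test (0.09 ± 0.20, adjusted p = 0.74 in edgeR). Over all 12366 genes tested, edgeR called 3682 higher and 3456 lower in SK-BR-3. Of the 28 lists, 16 passed camera with the preset correlation and 0 passed camera in limma with an estimated one (7 at an unadjusted p under 0.05), against 23 by fry.

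Luminal and epithelial genes were lower and mesenchymal genes higher in MDA-MB-231 than in MCF7. Of 21 luminal genes 19 were lower in MDA-MB-231 and 1 higher, with a median log2 fold change of −5.57 (camera adjusted p = 2.4e-29, and adjusted p = 0.019 with an estimated correlation). KRT19, a keratin of simple epithelia, had 14116 counts in MCF7 and none in MDA-MB-231, at least 13422-fold lower. GATA3, a luminal transcription factor, had 2018 against 3, a ratio of 1919 (656 to 9312). Of 22 epithelial genes 17 were lower and 1 higher (adjusted p = 3.9e-18, and adjusted p = 0.062 with an estimated correlation). The splicing regulator ESRP1 was at least 649-fold and RAB25 at least 372-fold lower, and the tight junction gene CLDN3 was at −9.94 ± 0.36. Of 28 mesenchymal genes 26 were higher and 1 lower (adjusted p = 1.8e-17, and adjusted p = 0.062 with an estimated correlation). Their median was 5.43, and 4.26 with the 10 members at 0 in one group set to their bound.

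Among the mesenchymal genes ZEB1, a repressor of epithelial genes, MSN, MYL9 and COL4A2 had no count in MCF7 and were at least 93.4-, 142-, 91.9- and 57.3-fold higher in MDA-MB-231. Of 17 hypoxia genes 14 were higher and 0 lower (camera adjusted p = 1.6e-06, and adjusted p = 0.15 with an estimated correlation). CA9, which encodes a carbonic anhydrase, was at least 24.2-fold higher. NDRG1 rose by 5.28 ± 0.27 and ADM by 4.27 ± 0.39 on the log2 scale, and LOX had a ratio of 18.6 (6.24 to 91.1). Adjusted over the list alone, the counts were 19 lower luminal, 17 lower epithelial, 26 higher mesenchymal and 15 higher hypoxia genes. LDHB, IGFBP3, LY6K, C4BPB, GPX1 and PRSS21 had no count in MCF7 and were at least 2057-, 719-, 655-, 639-, 414- and 376-fold higher. GAGE12H, a member of a multigene family whose count is uncertain, was at least 388-fold higher. FOLR1 had a ratio of 13317 (2390 to 526005). C3orf14, SUSD3, PYCARD and SPTSSB had no count in MDA-MB-231 and were at least 783-, 743-, 758- and 709-fold lower. LXN, FBP1 and MLPH were lower by ratios of 14000 (2512 to 553076), 6464 (1159 to 255412) and 5043 (904 to 199305). TFF1 was at −11.08 ± 0.40. EPCAM was lower by −4.16 ± 0.23, EGFR higher by 5.96 ± 0.41, and ERBB2 did not pass (−0.60 ± 0.31, adjusted p = 0.097 in edgeR). In edgeR 4010 genes were higher and 3648 lower in MDA-MB-231. Of 28 lists 8 passed camera, 1 passed with an estimated correlation and 19 passed fry. LOX was not called by DESeq2 (adjusted p = 0.222).

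Against SK-BR-3, MDA-MB-231 was lower in every measured gene of the HER2 amplicon and higher in cell cycle genes. All 16 amplicon genes were lower, with a median log2 fold change of −4.16. ERBB2 was at 4.24 ± 0.231 CPM (SD, n = 2) against 453 ± 92.4, a log2 fold change of −6.73 ± 0.25. GSDMB was at −9.81 ± 0.32, PPP1R1B was at least 75.3-fold lower and TCAP was lower by a ratio of 286 (50.2 to 11412). Of 53 G2 and M phase genes 46 were higher and 1 lower, among them the mitotic kinesin KIF11 at 3.20 ± 0.24, NCAPD2 at 2.98 ± 0.25, KIF20B at 2.85 ± 0.20 and ANP32E at 2.83 ± 0.21. KRT19 had 21377 counts in SK-BR-3 and none in MDA-MB-231, at least 20387-fold lower. Of 22 epithelial genes 20 were lower and 1 higher, and of 13 apocrine genes 10 were lower and 2 higher.

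Further epithelial genes were RAB25 and OVOL1, at least 507- and 123-fold lower in MDA-MB-231, and CLDN3 at −9.47 ± 0.36. The apocrine genes AGR2 and SCGB2A2 were at least 928- and 317-fold lower. DHRS2 was at −12.44 ± 0.37 and SERHL2 was lower by a ratio of 926 (316 to 4498). Of 28 mesenchymal genes 18 were higher and 8 lower: ZEB1, AXL, a receptor tyrosine kinase gene, and COL4A1 were at least 93.1-, 51.8- and 35.0-fold higher and VIM, which encodes vimentin, was at 9.19 ± 0.38. The amplicon, G2 and M phase, epithelial, apocrine and mesenchymal lists had camera adjusted p-values of 9.4e-11, 3.2e-12, 2.0e-10, 1.1e-04 and 2.9e-04, and each had an adjusted p of 0.0497 with an estimated correlation. Adjusted over the list alone, 16 amplicon genes were lower, 47 G2 and M phase genes higher, 20 epithelial and 10 apocrine genes lower and 18 mesenchymal genes higher. PRSS21, FHL1, NR2F1, IGFBP6, OLFM1, SNCA and IGFBP4 had no count in SK-BR-3 and were at least 375-, 328-, 238-, 224-, 192-, 183- and 157-fold higher. SPINK5 had a ratio of 3004 (1028 to 14568). S100A8, BCAS1, SPINK8, AZGP1 and AC110619.2 (the last uncertain, since reads of overlapping genes cannot be told apart) had no count in MDA-MB-231 and were at least 5758-, 3590-, 1952-, 1592- and 1539-fold lower. S100A9 and TSTD1 were lower by ratios of 55351 (9933 to 2186350) and 12529 (2247 to 494971). EPCAM was lower by −4.25 ± 0.23 and EGFR higher by 1.46 ± 0.24. In total edgeR called 4078 genes higher and 3946 lower. Of 28 lists 10 passed camera, 7 passed with an estimated correlation and 21 passed fry.

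**Figure D1:**
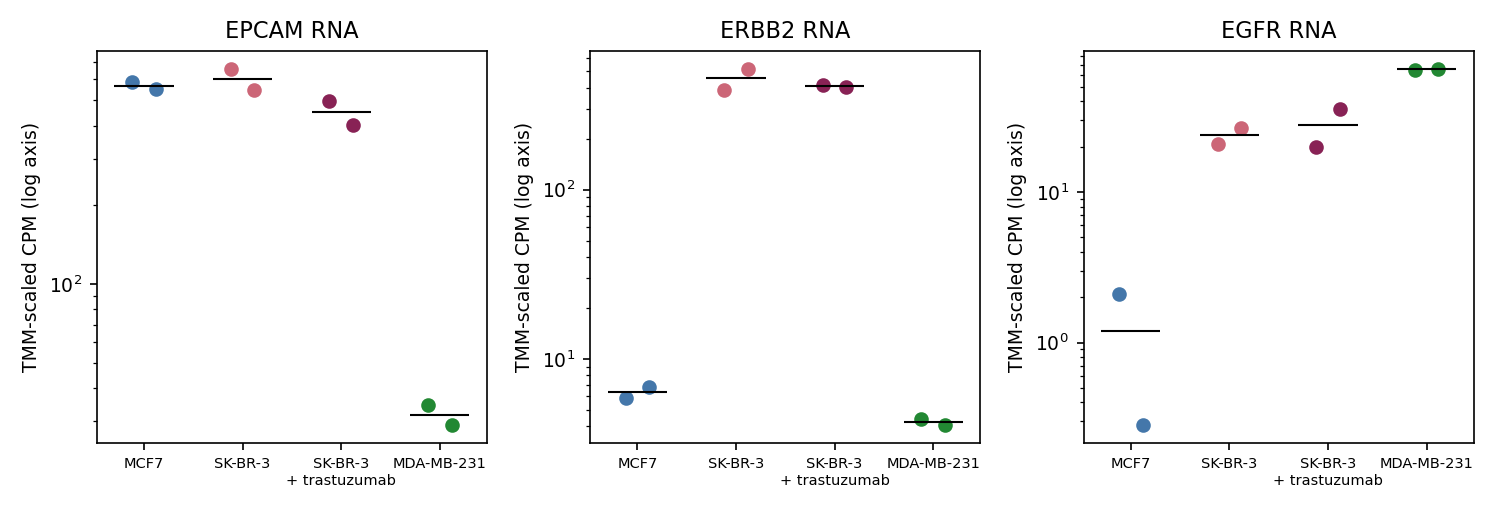
RNA of the antibody targets EPCAM, ERBB2 and EGFR in TMM-scaled CPM on log axes, with a point for each library (n = 2 per group) and a line at the group mean. ERBB2 lies at 453 and 408 CPM in untreated and treated SK-BR-3 against 6.33 in MCF7 and 4.24 in MDA-MB-231.

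The antibody tags asked whether surface protein differed between the lines. Mean EpCAM tags per barcode were 372 and 289 in MCF7, 119 and 23.6 in SK-BR-3, 381 and 271 in treated SK-BR-3 and 7.31 and 6.90 in MDA-MB-231. The groups differed (exact permutation F test on log2 means over all partitions of the 8 libraries into groups of 2, p = 0.0286). Mean HER2 tags were 143 and 94.7 in MCF7, 442 and 69.5 in SK-BR-3, 440 and 331 in treated SK-BR-3 and 7.76 and 7.72 in MDA-MB-231. They did not pass the exact test (p = 0.0857). Mean EGFR tags were 114 and 83.8, 52.0 and 7.45, 70.3 and 51.9, and 43.8 and 47.2 in the same order. They did not pass either (exact p = 0.152). The IgG control also differed between libraries, at 153 and 122 tags in MCF7, 20.9 and 2.94 in SK-BR-3, 52.8 and 39.8 in treated SK-BR-3 and 3.61 and 3.77 in MDA-MB-231. As a share of all tags HER2 took 69.8% and 67.1% in SK-BR-3, 46.6% and 47.7% in treated SK-BR-3, 18.3% and 16.1% in MCF7 and 12.4% and 11.8% in MDA-MB-231 (exact p = 0.00952, the smallest p these partitions allow). EGFR took 70.1% and 72.0% in MDA-MB-231 and between 7.19% and 14.5% elsewhere (exact p = 0.0286). EpCAM took 47.6% and 49.0% in MCF7, 40.4% and 39.1% in treated SK-BR-3, 18.7% and 22.8% in SK-BR-3 and 11.7% and 10.5% in MDA-MB-231 (exact p = 0.00952).

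Per IgG tag, a scale chosen after the data were seen, HER2 stood at 21.1 and 23.7 in SK-BR-3, 8.33 and 8.31 in treated SK-BR-3, 2.15 and 2.05 in MDA-MB-231 and 0.934 and 0.773 in MCF7 (exact p = 0.00952). EGFR stood at 12.1 and 12.5 in MDA-MB-231, 2.49 and 2.54 in SK-BR-3, 1.33 and 1.30 in treated SK-BR-3 and 0.742 and 0.684 in MCF7 (exact p = 0.00952). The raw EpCAM test lost its call without either MCF7 library (exact p = 0.0952 and 0.0762 for replicates 1 and 2), either MDA-MB-231 library (0.114 and 0.143) or either treated library (0.0857 and 0.0667). Per IgG tag EpCAM stood at 7.23 and 6.82 in treated SK-BR-3, the highest group by mean log2 ratio, and 5.67 and 8.05 in SK-BR-3. It stood at 2.43 and 2.36 in MCF7 and 2.03 and 1.83 in MDA-MB-231 (exact p = 0.0286). MCF7 was thus 1.24 times as high as MDA-MB-231 in EpCAM per IgG tag, against 46.1 times in raw tags. Without SK-BR-3 replicate 1 or 2 the raw HER2 test passed, and without SK-BR-3 replicate 1 so did raw EGFR. The group highest in raw HER2 tags was treated SK-BR-3 without replicate 1 and untreated SK-BR-3 without replicate 2.

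**Figure D2:**
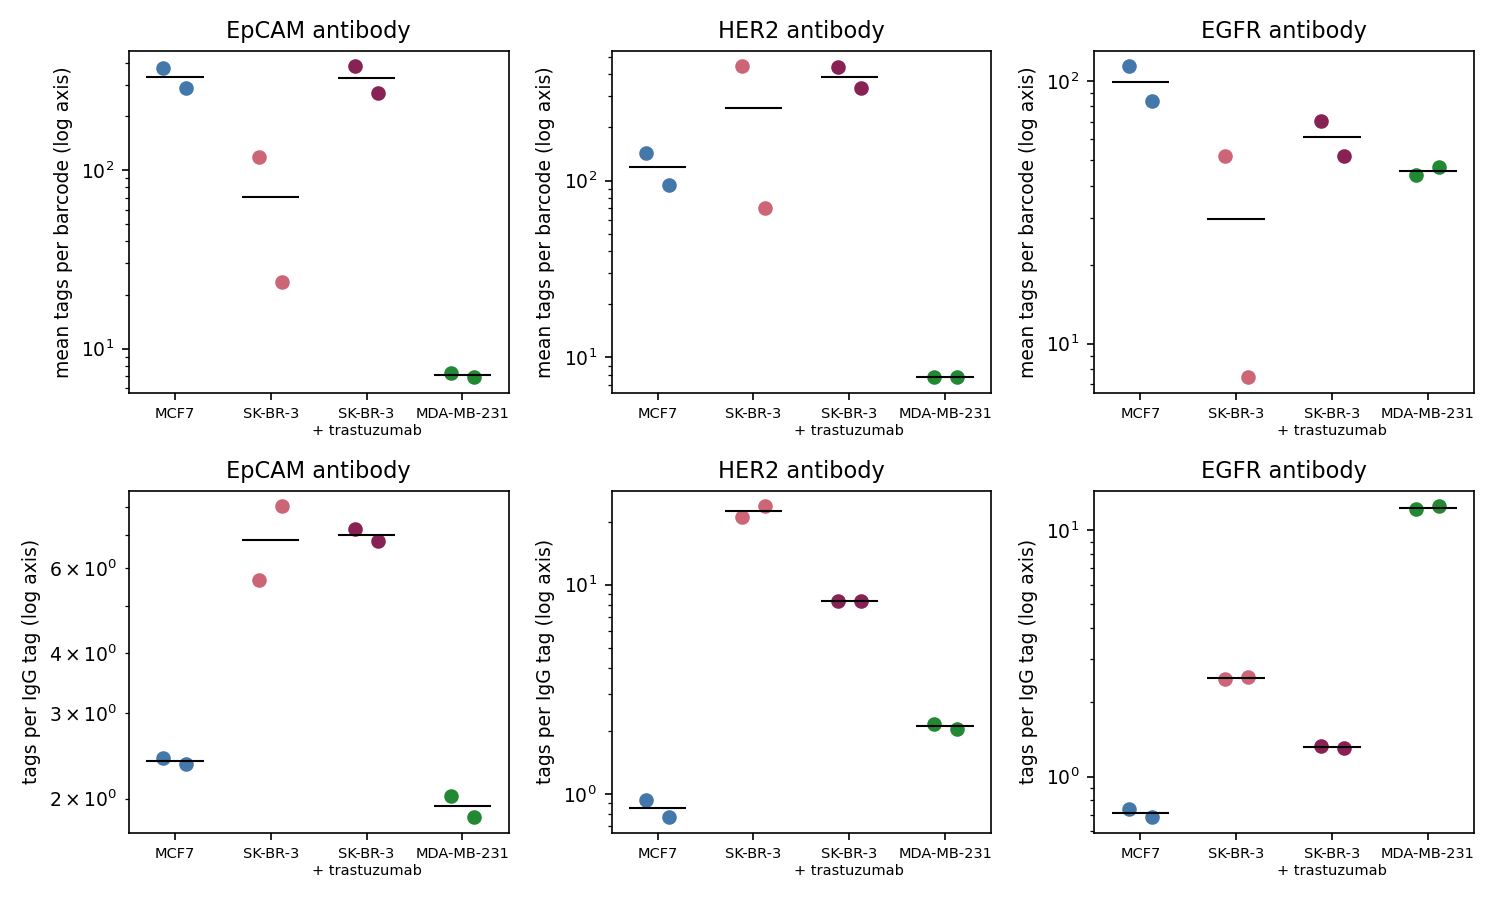
Antibody tags per library on log axes, as means per barcode (upper panels) and per IgG control tag (lower panels), with a point for each library (n = 2 per group) and a line at the group mean. SK-BR-3 has 22.4 HER2 tags per IgG tag, treated SK-BR-3 8.32, and MDA-MB-231 12.3 EGFR tags per IgG tag.

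Whether single cells with more of a transcript also carried more of its protein was tested within each library. The rank correlation of EPCAM, ERBB2 and EGFR RNA with the matching tag averaged 0.0903 over the 8 libraries (0.0334 to 0.150), above 0 in 8 of 8 (exact sign-flip test on library means, p = 0.0078, the smallest it can give). Mismatched gene and antibody pairs gave nearly the same value: the difference was 0.00297 ± 0.00990 (SD, n = 8), positive in 6 of 8 libraries (exact sign-flip p = 0.453). The total RNA and total tags of a barcode correlated at 0.566 on average (0.415 to 0.754), and HER2 and IgG tags at between 0.560 and 0.976. With tags as a share of the barcode's tags the matched mean was 0.00785, and given both totals it was 0.00434, neither past the threshold (exact sign-flip p = 0.297 and 0.516). Within MDA-MB-231, where 41.5% and 40.1% of barcodes had an EGFR count at median depths of 6836 and 6540.5 counts, the EGFR correlation was between 0.220 and 0.223. Within MCF7, where 0.677% and 0.101% of barcodes had an EGFR count at median depths of 2221 and 2573.5 counts, it was between −0.0166 and −5.6e-05. In SK-BR-3, where 5.64% and 8.52% of barcodes had an EGFR count, it was 0.100 and 0.0715. In treated SK-BR-3, where 8.33% and 12.6% had one, it was 0.199 and 0.235. The HER2 correlation was 0.0844 and 0.0506 in MCF7, where 1.89% and 2.42% of barcodes had an ERBB2 count. In SK-BR-3, where 52.9% and 68.6% had an ERBB2 count, the HER2 correlation was 0.0864 and 0.0610. These values for single antibodies were not set against mismatched pairs. Averaged over the antibodies, matched minus mismatched was 0.0219 and 0.00306 in MDA-MB-231 and −0.00134 and 0.00911 in treated SK-BR-3. It was 0.00106 and 0.00248 in MCF7 and −0.0132 and 0.000723 in SK-BR-3.

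Genes induced by interferon had the largest median fold change among the 28 lists tested in SK-BR-3 cells exposed to trastuzumab. Of 30 interferon response genes 27 rose and 0 fell, with a median log2 fold change of 4.08 (camera adjusted p = 1.2e-45, and adjusted p = 0.0048 with an estimated correlation). The count was also 27 when adjusted over the list alone. IFI6 went from 13.7 ± 1.68 to 938 ± 88.7 CPM (SD, n = 2), MX1, which encodes an antiviral GTPase, from 1.70 ± 0.480 to 150 ± 9.11 and IFIT1 from 1.02 ± 0.959 to 137 ± 31.2, log2 fold changes of 6.09 ± 0.24, 6.44 ± 0.31 and 7.01 ± 0.37 (SE). IFI44L had 677 counts against 3 (ratio 269, counting interval 91.7 to 1308), OAS2 282 against 2 (168, 46.1 to 1395) and HERC5 258 against 3 (103, 34.7 to 501), while IFI44 rose by 6.49 ± 0.35 and IFIT3 by 5.77 ± 0.38. The members not called, named after their values were seen, were IRF1 (0.41), USP18 (0.42) and LGALS3BP (0.29). The mitochondrial share of the treated libraries was 6.97% and 7.49%, against 2.11% and 5.07% in the untreated, which applies beside every gene group described for treated cells. Of 26 mitochondrially encoded genes 4 rose and 1 fell (3 and 1 adjusted over the list alone), and their list did not pass camera in limma (adjusted p = 0.050, and adjusted p = 0.83 with an estimated correlation). It passed without SK-BR-3 replicate 2 (adjusted p = 3.5e-08 in limma) and without treated replicate 1 (adjusted p = 0.0108 in limma), but not without SK-BR-3 replicate 1 (0.812) or treated replicate 2 (0.506). In limma it also passed with no low-count filter (adjusted p = 0.0308), with all barcodes (0.0494), with at least 1000 genes (0.0329), thinned (0.00634), without undetermined or shared barcodes (0.0479) and with only the compared groups (0.0200). It did not pass with median-of-ratios scaling (adjusted p = 0.0516 in limma) or by fry (0.453).

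Most treated barcodes held several interferon counts. Thinned to 1000 counts, which left out 10 and 18 treated and 20 and 77 untreated barcodes, 92.1% and 89.1% of treated barcodes held at least 3 counts of the list, against 8.26% and 11.1% of untreated ones. In the other lines, the share was 22.4% and 25.4% in MCF7 and 6.42% and 8.47% in MDA-MB-231. At least 1 list count was found in 98.9% and 99.4% of treated and 62.6% and 67.6% of untreated thinned barcodes, and in 99.6% and 99.9% against 87.8% and 87.3% before thinning, at median depths of 2535.5 and 3018.5 against 2500.5 and 2340.

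**Figure D3:**
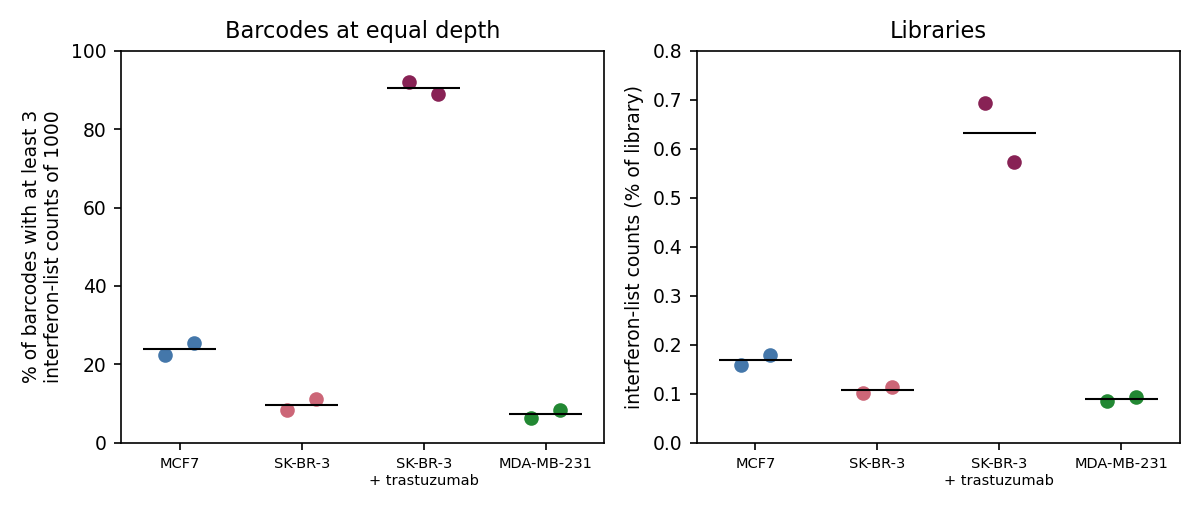
Left, percent of barcodes with at least 3 counts of the interferon response list after thinning to 1000 counts; right, list counts as a percent of all counts in the library. Points are libraries (n = 2 per group) and lines are group means; treated SK-BR-3 libraries lie at 92.1% and 89.1% on the left, and all other libraries at or below 25.4%.

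Some genes of the MHC class I pathway and some targets of FOXO factors, which are active when PI3K signalling is low, also rose. Of 15 antigen presentation genes 7 rose and 0 fell (camera adjusted p = 7.8e-05, and adjusted p = 0.14 with an estimated correlation; 8 adjusted over the list alone). The immunoproteasome genes PSMB9 and PSMB8 were at 1.99 ± 0.20 and 1.72 ± 0.22, HLA-B at 2.13 ± 0.26, and HLA-F had 19 counts against 3 (ratio 7.55, 2.22 to 39.9). HLA genes share reads with each other, so their counts are uncertain. Of 18 FOXO targets 10 rose and 0 fell (adjusted p = 5.2e-06, and adjusted p = 0.14 with an estimated correlation; 12 higher and 1 lower adjusted over the list alone). Among them were KLHL24 at 1.87 ± 0.23, YPEL3 at 1.78 ± 0.22, TXNIP, which encodes a thioredoxin inhibitor, at 1.72 ± 0.19 and PIK3IP1, an inhibitor of PI3K, at 1.47 ± 0.36.

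Some genes of the S phase, of the G2 and M phases, of ribosome biogenesis and of oxidative phosphorylation fell in treated cells. Of 43 S phase genes 16 fell and 1 rose (camera adjusted p = 2.2e-05, and adjusted p = 0.14 with an estimated correlation; 21 lower and 2 higher adjusted over the list alone). Among them were MCM2 at −2.04 ± 0.51, CLSPN at −1.67 ± 0.22, FEN1 at −1.56 ± 0.24 and DTL at −1.51 ± 0.32. Of 53 G2 and M phase genes 14 fell and 0 rose (adjusted p = 1.3e-04, and adjusted p = 0.19 with an estimated correlation; 16 lower adjusted over the list alone). Among those called were the proliferation marker MKI67 at −1.84 ± 0.23, TUBB4B, uncertain as one of several similar tubulin genes, at −2.16 ± 0.22, CKAP2L at −1.41 ± 0.28 and TACC3 at −1.21 ± 0.25. Of 21 genes of ribosome biogenesis driven by MYC 9 fell and 2 rose (adjusted p = 0.0064, and adjusted p = 0.37 with an estimated correlation; 10 lower adjusted over the list alone). The nucleolar genes NOP56 and NCL were at −1.77 ± 0.23 and −1.80 ± 0.27 and ODC1 at −2.10 ± 0.28, while MYC itself rose by 1.08 ± 0.24. Of 40 nuclear genes of oxidative phosphorylation 11 fell and 0 rose (adjusted p = 1.8e-05, and adjusted p = 0.51 with an estimated correlation; 11 adjusted over the list alone). That list did not pass fry (adjusted p = 0.115). Called members included NDUFA6 at −1.16 ± 0.23, ATP5B at −1.08 ± 0.21, UQCRQ at −1.05 ± 0.32 and ATP5G3 at −0.98 ± 0.23.

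Of 25 cholesterol synthesis genes 6 fell and 0 rose (camera adjusted p = 0.0074, and adjusted p = 0.31 with an estimated correlation; 6 adjusted over the list alone). Called members included ACAT2 at −1.93 ± 0.27, LDLR, the lipoprotein receptor, at −1.32 ± 0.30, MVK at −1.25 ± 0.35 and EBP at −1.22 ± 0.19. Of 13 fatty acid synthesis genes 2 fell and 0 rose (3 lower adjusted over the list alone), and that list did not pass (adjusted p = 0.27, and adjusted p = 0.51 with an estimated correlation). Of 22 glycolysis genes 10 fell and 3 rose (adjusted p = 0.032, and adjusted p = 0.31 with an estimated correlation; the counts were also 10 and 3 adjusted over the list alone). With only the compared groups that list did not pass camera (adjusted p = 0.0933 in limma). The glucose transporter SLC2A1 was at −1.37 ± 0.21 and LDHB at −1.36 ± 0.21, while PFKFB3 and PGAM1 rose by 1.99 ± 0.41 and 1.30 ± 0.24. Of 18 genes of the integrated stress response 6 fell and 1 rose (adjusted p = 0.032, and adjusted p = 0.31 with an estimated correlation; 7 lower adjusted over the list alone). The named members were SLC3A2 at −1.67 ± 0.20, PSAT1 at −1.35 ± 0.26, PPP1R15A at −1.25 ± 0.21 and ATF3 at −1.24 ± 0.18. Camera calls (limma) of the glycolysis list were lost without SK-BR-3 replicate 1 (adjusted p = 0.0732) or treated replicate 2 (0.110). In limma the stress response call was lost without SK-BR-3 replicate 2 (0.130) or treated replicate 2 (0.239), and that of the cholesterol list without treated replicate 2 (0.147).

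**Figure D4:**
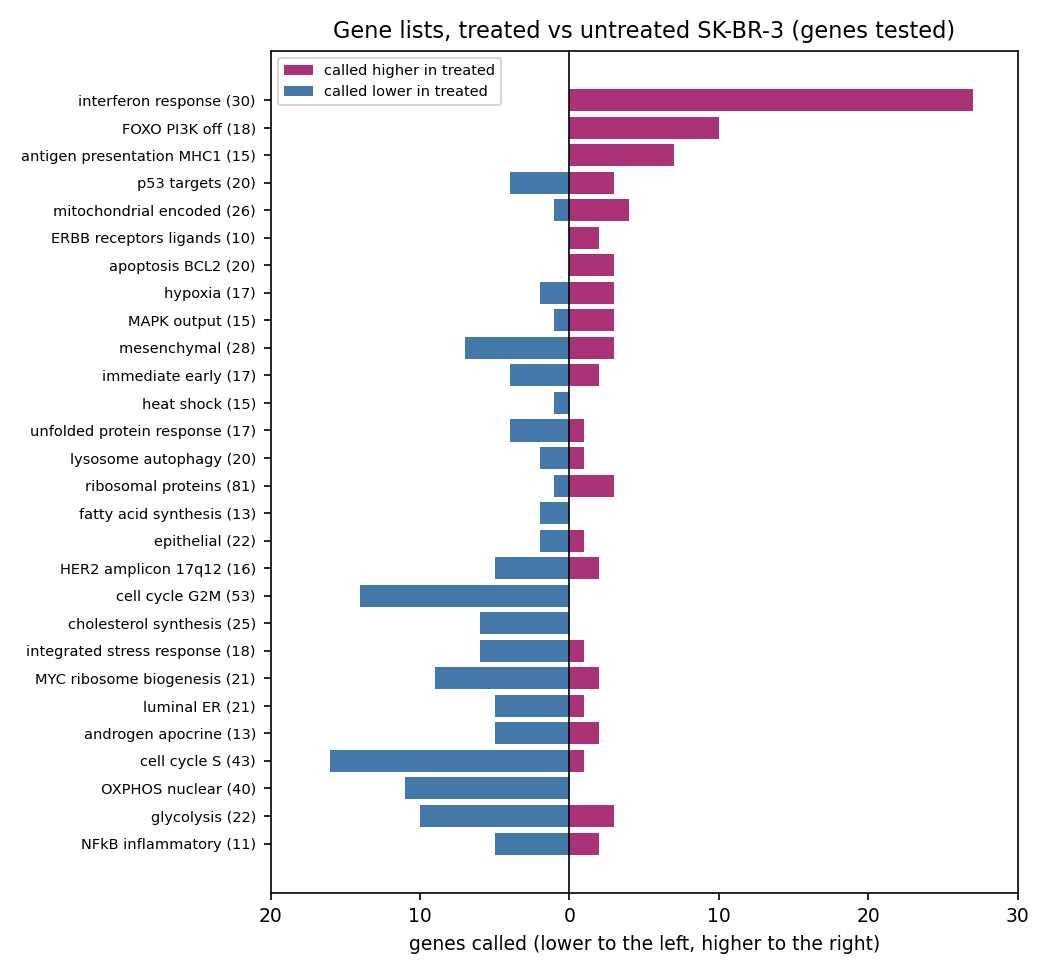
Genes of each fixed list that edgeR called higher (right) or lower (left) in trastuzumab-treated than in untreated SK-BR-3, with the number tested in parentheses and lists ordered by median log2 fold change. The interferon response list has 27 of 30 genes called higher.

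RNA of the antibody targets did not pass the test: ERBB2 was at 408 ± 7.89 CPM (SD, n = 2) in treated and 453 ± 92.4 in untreated SK-BR-3 (log2 fold change −0.15 ± 0.18, adjusted p = 0.62). EPCAM (−0.43 ± 0.20, adjusted p = 0.14) and EGFR (0.30 ± 0.27, adjusted p = 0.49) did not pass edgeR's test either. EPCAM passed without treated replicate 1 (−0.59, adjusted p = 0.0383 in edgeR). Fold changes were ranked from the lowest among called genes with a mean of at least 50 CPM in the higher group and no library overlap. BMP7, which encodes a bone morphogenetic protein, was at −3.11 ± 0.29 and mammaglobin SCGB2A2 at −2.66 ± 0.28. The mitotic transcription factor FOXM1 was at −2.55 ± 0.26 and RP6-109B7.3, uncertain where genes overlap, at −2.44 ± 0.40. PELP1 was at −2.35 ± 0.27, FAM65C at −2.17 ± 0.23, TUBB4B at −2.16 ± 0.22 and TGFB3 at −2.14 ± 0.25. Some called genes under that CPM limit, such as IL8, had lower fold changes. In total edgeR called 2453 genes of 12366 tested, 1130 higher and 1323 lower, 695 and 668 of them by over 2-fold. The chi-square per degree of freedom between replicates was 12.1 in untreated and 13.1 in treated SK-BR-3. It was 4.69 in MCF7 and 6.55 in MDA-MB-231, so the shared estimate of spread may be too small for this comparison. With only the compared groups in the fit, edgeR called 1750 genes. The count of 2453 was 1557 without SK-BR-3 replicate 1, 1568 without SK-BR-3 replicate 2 and 1452 with DESeq2. Leaving out a single library also ended edgeR's calls of HLA-F (adjusted p = 0.202 without SK-BR-3 replicate 1, 0.115 without treated replicate 1) and UQCRQ (0.229 and 0.145 without SK-BR-3 replicates 1 and 2, 0.0653 without treated replicate 1). Likewise edgeR did not call LDLR and MVK (adjusted p = 0.111 and 0.0553 without SK-BR-3 replicate 2), or MCM2, DTL, CKAP2L and PIK3IP1 (0.0851, 0.0704, 0.0679 and 0.0611 without treated replicate 2).

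HER2 tags relative to EpCAM tags were lower after treatment. The ratio was 3.73 and 2.94 in untreated and 1.15 and 1.22 in treated SK-BR-3, 2.79 times lower as geometric means, with a pooled SD of 0.15 on the log2 scale. This ratio was chosen after the data were seen. HER2 tags per EGFR tag were 8.50 and 9.33 in untreated and 6.25 and 6.37 in treated libraries, 1.41 times lower. Raw EpCAM tags were 6.08 times as high in treated as in untreated libraries, without overlap, and raw HER2 tags were 2.18 times as high. The raw HER2 means of untreated and treated libraries overlapped. Since 2 libraries against 2 cannot give an exact p below 0.333, these differences were not tested.

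Marker sets fixed before the data were examined were summed per library. Markers of SK-BR-3 summed to 9882 and 8199 CPM there and to 643 or less in MCF7 and MDA-MB-231. Markers of MDA-MB-231 summed to 2328 and 2349 CPM there, 1864 and 1453 in SK-BR-3 and 352 and 310 in MCF7. Markers of MCF7 summed to 4495 and 4408 CPM there, 4169 and 3903 in SK-BR-3 and 26.5 and 31.3 in MDA-MB-231. Most of the SK-BR-3 sum came from KRT19, with 11149 and 10228 of the 12292 and 11506 counts. In MCF7 KRT19 gave 5349 and 8767 of 10745 and 15534 counts. The sum therefore does not show that SK-BR-3 expressed the other MCF7 markers at a similar level. In treated SK-BR-3 the markers of SK-BR-3 summed to 7095 and 7500, those of MCF7 to 3579 and 2438, and those of MDA-MB-231 to 884 and 1221 CPM. Haematopoietic markers reached at most 6.69 CPM and fibroblast or endothelial markers at most 3.77 CPM in any library.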

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

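All checks in this part were chosen after the shared barcodes had been seen. Barcodes that held under 500 genes entered only the alternatives with all barcodes. Of those in MCF7 replicate 1, 90 also occurred in MCF7 replicate 2. Of those in MDA-MB-231 replicate 1, 5 occurred in MDA-MB-231 replicate 2. In all, the MCF7 libraries shared 94 barcodes, 1669.8 times the 0.0563 that random barcodes of 12 bases would give, which argues against chance repeats. The shared barcodes lay at a median percentile of 86.2 (82.6 to 90.5) by total count in replicate 2, held a median of 322 counts in replicate 1 against 6024 in replicate 2, and took 1.55% of the counts of replicate 1. A candidate explanation, found and tested on the same data, is carry-over of reads from deep barcodes of replicate 2 into replicate 1. Each MCF7 library shared 1 barcode with each library of the other groups. That argues against uneven barcode synthesis common to all libraries as the source of the 94. Uneven synthesis particular to the MCF7 pair was not tested, nor was any biological explanation. The treated SK-BR-3 libraries shared 12 barcodes and the untreated ones 1.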

How the results depend on the processing

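The ratio to the IgG tag and the removal of shared or undetermined barcodes were chosen after the results were seen. Across edgeR settings the calls for treated SK-BR-3 ran from 1662 (thinned) to 2698 (replicate block), with 1452 in DESeq2 and 1557 to 2225 without single libraries. Cell-line counts stayed within 1.5 times (5821 to 6454, 6177 to 6842 and 7094 to 7252 without single libraries). Among the genes named, 18 of 799 values of the treated comparison fell below the threshold, 1 rose above it and 0 reversed, and LOX (DESeq2, adjusted p = 0.222) was the only loss between lines. Apart from the antibody targets, these genes were chosen in the same data for large changes, so their stability does not describe all calls. Of the 2453 treated calls, 1421 were shared with DESeq2, 1524 with thinning, 1723 with only the compared groups and 2429 with the replicate block. Of 28 treated lists 10 passed camera, 1 passed with an estimated correlation, 14 by fry (9 of the 10 among them), and 8 to 13 without single libraries (7 to 10 of the 10). The replicate numbers were not taken to pair the samples, since correlations of deviations were not all above 0.1 (0.16, 0.34, −0.17, 0.19, 0.03 and 0.17). With the number as a block 8 lists passed (glycolysis 0.0744 and the stress response 0.0777 did not), the cell-line counts were 7237, 7832 and 8149, and the raw EpCAM tag test lost its call (exact p = 0.0833), while HER2 (0.167) and EGFR (0.208) stayed above the threshold. EpCAM tags gave exact p = 0.0286 with all barcodes, with at least 1000 genes and per IgG tag, each with treated SK-BR-3 in place of MCF7 as the highest group, and 0.0286 to 0.143 without single libraries. HER2 tags passed as a share and per IgG tag (exact p = 0.00952 for both, SK-BR-3 highest) and ran from 0.0190 to 0.105 without single libraries. EGFR tags passed as a share (exact p = 0.0286) and per IgG tag (0.00952), with MDA-MB-231 highest, and ran from 0.00952 to 0.486. The RNA and protein correlation of 0.0903 fell to 0.00785 with tag shares and 0.00434 given both totals. The mixed share of the multi-omics library was 3.22% at a threshold of 95% and 1.94% with at least 1000 genes. The ratio of median human counts was 0.845 with at least 1000 genes, that of human genes 1.04 after thinning, and that of mouse counts 0.951 with all barcodes. The cause of these changes was not tested, except that thinning and omitted libraries leave fewer counts or samples. Depth limits genes such as MCM2 (7 counts in treated cells) and HLA-F (3 in untreated cells).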

Other observations

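The tests of explanations for the interferon and HER2 tag patterns below were chosen after those patterns were seen. Only the predictions on the mitochondrial share and on few barcodes were written before their checks were run. Immediate early, NF-κB and lysosomal genes were higher in SK-BR-3 than in MCF7. Of 17 immediate early genes 13 rose and 1 fell (13 and 1 adjusted over the list alone; median log2 fold change 1.91, camera adjusted p = 1.5e-05 in limma, and adjusted p = 0.21 with an estimated correlation). Among them KLF2, a transcription factor gene, was at least 41.1-fold higher, and FOSB, DUSP1 and ATF3 were at 4.21 ± 0.33, 3.96 ± 0.25 and 3.93 ± 0.21. Of 11 NF-κB and inflammatory genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; median 2.31, adjusted p = 0.0012 in limma, and adjusted p = 0.11 with an estimated correlation). The chemokine gene CCL20 was at least 18.1-fold higher, TNFAIP3, which encodes an inhibitor of NF-κB signalling, was at 5.17 ± 0.42, TNFAIP2 at 4.60 ± 0.46, and IL8 had a ratio of 23.7 (7.80 to 118). Of 20 lysosome and autophagy genes 15 rose and 3 fell (16 and 3 adjusted over the list alone; median 1.02, adjusted p = 0.0012 in limma, and adjusted p = 0.21 with an estimated correlation), with the cathepsin gene CTSZ at least 840-fold higher, GABARAPL1 at 4.93 ± 0.33, CTSD at 4.05 ± 0.25 and CTSL at 2.36 ± 0.43.

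In treated SK-BR-3 cells several NF-κB genes fell, although their list did not pass. Of 11 genes 5 fell and 2 rose (6 and 3 adjusted over the list alone; camera adjusted p = 0.050 in limma, and adjusted p = 0.31 with an estimated correlation). IL8 was lower by a ratio of 19.8 (6.52 to 98.5), TNFAIP3 was at −3.01 ± 0.34, CCL20 at −2.48 ± 0.57 and RELB at −1.55 ± 0.37. The list passed without SK-BR-3 replicate 1 (adjusted p = 0.0252 in limma) or replicate 2 (0.0493), with no low-count filter (0.00913), with all barcodes (0.0494), without undetermined or shared barcodes (0.0479), with only the compared groups (0.0159) and by fry (0.00234). It did not with median-of-ratios scaling (adjusted p = 0.0516 in limma), at least 1000 genes (0.0992), thinning (0.349) or without treated replicate 1 (0.0928) or 2 (0.110). The call of CCL20 was lost without SK-BR-3 replicate 1 (adjusted p = 0.135 in edgeR). Of 16 genes of the HER2 amplicon 5 fell and 2 rose (also adjusted over the list alone), with PPP1R1B at −3.03 ± 0.49, PSMD3 at −0.98 ± 0.18, MED1 at −0.89 ± 0.20 and GRB7, which encodes an adaptor protein that binds HER2, at 1.00 ± 0.20. That list did not pass either (adjusted p = 0.078 in limma, and adjusted p = 0.31 with an estimated correlation), but it did without SK-BR-3 replicate 1 (0.0472), with no low-count filter (0.0308) and by fry (0.0145). The mitochondrial share was 6.97% and 7.49% in treated and 2.11% and 5.07% in untreated libraries.

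Interferon response genes were higher in treated SK-BR-3 libraries. A few strongly responding cells are argued against, since at least 89.1% of the barcodes of each treated library held 3 or more list counts at equal depth. Free RNA was not measured in these libraries, but it would have to supply most list counts, since the median barcode held 6 and 5 per 1000 against means of 6.79 and 5.79, and in the separate mixture libraries the other species gave a median of at most 2.24%. Library depth is argued against by a median log2 fold change of 4.08 with all libraries thinned to the smallest, and a higher mitochondrial share by barcodes at or below the higher untreated median share, where the list share in treated libraries was at least 4.88 times the untreated one. A response to the antibody remains a hypothesis, and differences in culture or library preparation between treated and untreated cells, which the design does not separate from treatment, could also give the pattern.

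HER2 tags were lower relative to EpCAM tags in treated SK-BR-3 libraries. If tag yield scaled both antibodies alike, the ratio would not depend on it, but this was not tested. The ratio was 3.73 and 2.94 in untreated libraries with medians of 495 and 58 tags per barcode. It was 1.15 and 1.22 in treated ones with 354.5 and 283.5, so it did not follow tag yield across these libraries. As geometric means the ratio was 2.79 times higher in untreated libraries. HER2 was 2.69 times higher there per IgG tag and only 1.41 times per EGFR tag. Subtracting IgG tags left a difference of at least 2.56 times, which cannot exclude unspecific binding. The role of the IgG tag is not stated, and MCF7 held fewer HER2 than IgG tags (0.934 and 0.773 per IgG tag). IgG took 5.59% and 5.74% of tags in treated and 3.30% and 2.84% in untreated SK-BR-3 libraries. A few barcodes are argued against by the median ratio per barcode, at least 2.55 times higher in each untreated library. EGFR per EpCAM tag was also lower in treated libraries (0.184 and 0.191 against 0.438 and 0.315), while EpCAM per IgG tag overlapped (7.23 and 6.82 against 5.67 and 8.05). Which tags moved stays open, since each ratio depends on its reference. Loss of HER2 from the surface, trastuzumab covering the site that the HER2 antibody binds, a change in EpCAM and unspecific binding are possible explanations. Treatment was not separated from culture or library differences.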
